A study of Mus musculus with 6 samples.

How the data were processed

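Whole hearts of male C57BL/6 mice were profiled by RNA sequencing in 2 groups of 3 libraries. Per the labels' protocols, the mice of the exercise hypertrophic preconditioning group (EHP) followed a swimming programme that spanned 21 days, from sessions of 15 minutes up to sessions of 90 minutes, 2 sessions a day on 5 days of each week, and their hearts were taken 1 week after the last swim. The sedentary group (Sed) was kept without swimming. The labels describe the profiled RNA as long noncoding RNA (lncRNA), that is, RNA without a protein product. They give each library a number of its own but do not say that each number is 1 animal, so the p-values measure the spread between these libraries.

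The authors deposited a table of raw read counts per Ensembl mouse transcript, with 46746 transcripts in rows and 1 column per library. Per the submitters' processing notes, HISAT2, StringTie and DESeq2 were used with the genome build mm9. Some transcript IDs appear to be from later annotation releases than that build. Which build and release the counts rest on could therefore not be settled here. The versions of these tools, the program that counted the reads, the strand setting and the annotation release are not given in the sources used here. The second deposited file is the authors' DESeq2 comparison of EHP with Sed. Per the file headers, it holds for each transcript a mean normalised signal over the libraries, a log2 fold change with its standard error, a p-value and an adjusted p-value, all computed by the authors. It lists 27884 transcripts. The counts of every listed transcript sum to at least 10 over the 6 libraries, and no unlisted transcript has a sum above 9.

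Both files name transcripts by Ensembl transcript ID only and do not pair them with gene names. Of the 46746 IDs, 0 matched the 2 gene name tables used here, which list genes and not Ensembl transcripts. Gene symbols, positions and biotypes are therefore not given. The 37 gene lists and cell type marker lists fixed before the data were examined, the planned test of the cardiac lncRNA Mhrt and the planned lncRNA subset were not analysed here. Isoforms of a gene, overlapping transcripts and antisense partners are separate rows of the table. How reads shared between such transcripts were assigned is not given in the sources used here, so a call on 1 transcript is uncertain as to which of its neighbours supplied the reads.

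Counts were tested with edgeR 4.0.16 in R 4.3.3. Transcripts with low counts were removed with filterByExpr, which left 20044. Libraries were scaled by trimmed mean of M-values (TMM), dispersions were estimated, and EHP was compared with Sed by the quasi-likelihood F test (glmQLFit, glmQLFTest) with group as the only term. Benjamini-Hochberg adjusted p-values under 0.05 were taken as calls. The standard error of a log2 fold change was taken as its size divided by the square root of F. CPM values are counts per 1000000 counts of the tested transcripts after TMM scaling, and log2 CPM values used a prior count of 2. A transcript described as rising or falling passed this test.

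The rule for named transcripts was set before the data were examined. Among calls with an average abundance of at least 1 in log2 CPM and no overlap between the 3 EHP and 3 Sed libraries, it took the 10 largest rises and the 10 largest falls. The abundance used was edgeR's fitted average over the 6 libraries, not the mean of their log2 CPM values. A high level in 1 group lifts this average, and ENSMUST00000218552 passed narrowly, at 1.04. Because no gene names were attached, only the IDs of the 2 largest in each direction are printed, and the others are summarised.

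The edgeR and DESeq2 1.42.0 fits were tested on simulated counts for the same 20044 transcripts, with library sizes and dispersions taken from the real libraries and 200 transcripts changed by known amounts. edgeR recovered 74% of 100 transcripts changed 2-fold and 91% of 100 changed 4-fold, with the sign right in each recovered case and 20 false calls. DESeq2 recovered 66% and 84%, with 16 false calls. For both fits the false calls were a larger share of the simulated calls than the 0.05 the threshold aims at. In the real libraries 37.2% of the tested transcripts were called, a far larger share than was changed in the simulation. These rates therefore may not carry over to the real calls.

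Alternatives set before the data were examined were DESeq2 in place of edgeR, other library scalings, no filter and a stricter filter on low counts, the replicate number as a block, leaving out each library, and a looser threshold. Every library thinned to the smallest total, DESeq2 on the transcripts of the authors' table, and a fit without the 50 most abundant transcripts were added after seeing the data. Library totals ranged from 6757585 to 9532515 counts. A floor of 3 counts was equal to 0.314 to 0.457 CPM per library. Counting intervals are exact 95% binomial intervals and cover counting error only, since the reads carry no molecular identifiers in the sources used here.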

Results

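The hearts of mice that had completed a swimming programme spanning 21 days and then rested for 1 week were compared with the hearts of sedentary mice, to ask which transcripts differed at that time. Each group had 3 libraries. The Sed libraries held 9394793, 9532515 and 8703851 counts, and the EHP libraries held 6766176, 6757585 and 6879244. The mean was 9210386 ± 444044 in Sed and 6801002 ± 67896 in EHP (SD, n = 3 each). Every EHP library thus held fewer counts than every Sed library. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow. These are counts assigned to the transcripts of the table, and totals of sequenced reads were not examined. Depth below means these counts. Of the 46746 transcripts in the table, 12400 had no count in any library and 20044 had enough counts to be tested. No batch or date was labelled.

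The groups separated clearly. On the first principal component of log2 CPM, which held 60.4% of the variance, the 3 EHP libraries lay between 37.4 and 47.0 and the 3 Sed libraries between -47.6 and -38.4. Sed replicate 2 stood apart on the second, which held 12.1%: it lay at -34.8, against 18.7 and 20.7 for Sed replicates 1 and 3 and -10.9 to 5.39 for the EHP libraries. Pearson's r of log2 CPM across transcripts was 0.979 to 0.983 for pairs of libraries within a group and 0.941 to 0.954 for pairs between groups. Transcripts are not independent replicates, so these r values describe the libraries only. No 2 libraries were copies of each other. The chi-square of the counts per degree of freedom was 2.80 to 3.93 for pairs within EHP and 7.22 to 12.5 for pairs within Sed. Sampling noise alone would give 1. This value also grows with the counts, which were higher in Sed.

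After swimming and rest, 3739 transcripts were higher and 3717 were lower than in sedentary hearts, which together was 37.2% of the 20044 tested (edgeR quasi-likelihood test, adjusted p under 0.05). The typical change was modest: the median called transcript differed 1.60-fold, and 2920 of the 7456 calls were under 1.5-fold. Larger changes were mostly increases. At 2-fold or more, 1278 transcripts rose and 464 fell. At 4-fold or more, 149 rose and 33 fell. The 3 EHP libraries lay wholly above or wholly below the 3 Sed libraries for 9878 transcripts, or 49.3% of those tested, where chance gives 10%. Of the 7456 calls, 7213 were separated in this way. No call that was tested again changed its sign in the 15 alternative fits, in which the number of calls ranged from 5652 to 7787. Without Sed replicate 2 it was 6796.

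**Figure D1:**
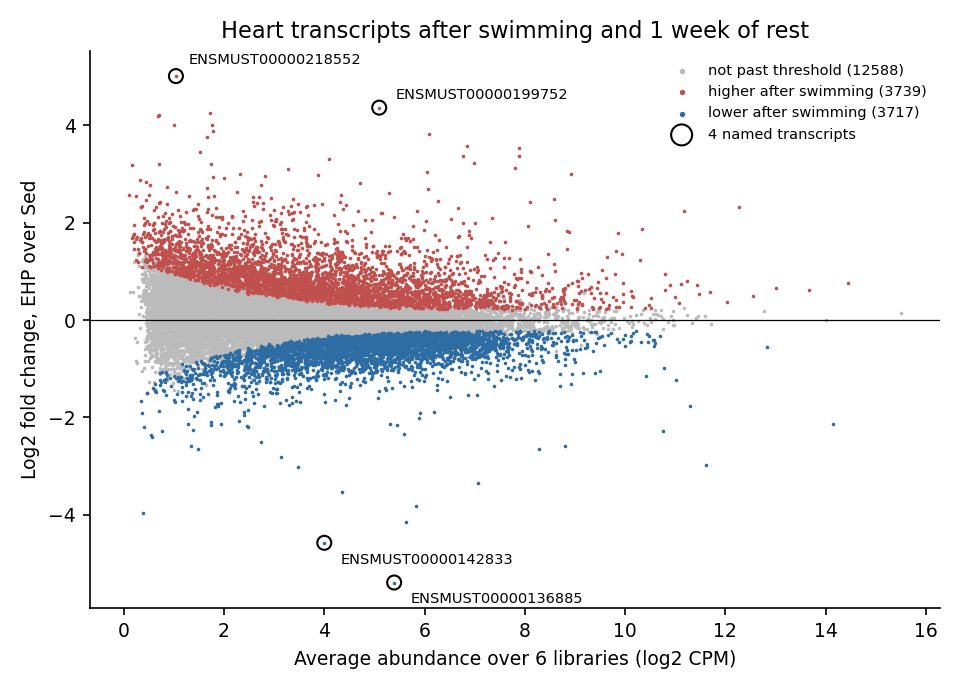
Log2 fold change (EHP over Sed, vertical axis) against average abundance in log2 CPM (horizontal axis) for the 20044 tested transcripts, 1 point each. Red points are the 3739 transcripts that rose, blue points the 3717 that fell, grey points did not pass adjusted p 0.05, and black rings mark the 4 named transcripts.

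The largest rise was that of ENSMUST00000218552, a scarce transcript that was close to undetected in sedentary hearts. Its level was 4.02 ± 1.21 CPM in EHP and 0.105 ± 0.105 CPM in Sed (SD, n = 3 each), and its counts were 35, 20 and 26 against 1, 2 and 0. The fitted log2 fold change was 5.02 (SE 0.57, edgeR adjusted p = 2.9e-05). All of the Sed libraries lay under the 3-count floor, so the size rests on 3 Sed counts. The ratio of pooled counts, 81 against 3, was 36.6 after scaling by the total counts of each group. Its exact 95% counting interval, scaled in the same way, was 12.1 to 181. The fitted log2 value ranged from 4.51 without Sed replicate 3 to 5.90 with all libraries thinned to equal depth.

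ENSMUST00000199752 rose from 3.23 ± 0.53 CPM in Sed to 67.0 ± 5.76 CPM in EHP (SD, n = 3 each), a log2 fold change of 4.37 (SE 0.14, edgeR adjusted p = 3.51e-10), or 20.6-fold. Its counts were 483, 426 and 445 in EHP against 36, 27 and 26 in Sed. It was the better measured of the 2 named rises, and its log2 fold change stayed between 4.28 and 4.50 over 15 alternatives.

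ENSMUST00000136885 showed the largest fall. It was 1.87 ± 0.57 CPM in EHP and 79.9 ± 69.5 CPM in Sed (SD, n = 3 each), a log2 fold change of -5.39 (SE 0.78, edgeR adjusted p = 0.000184). The sedentary libraries differed widely from each other, with 71.9, 14.7 and 153 CPM in Sed replicates 1, 2 and 3. The lowest of them was still above the 1.33 to 2.46 CPM of the EHP libraries. Without Sed replicate 3 the log2 fold change was -4.54, the smallest in 15 alternatives, and the largest was -5.89.

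ENSMUST00000142833 fell from 28.7 ± 28.4 CPM in Sed to 1.19 ± 0.82 CPM in EHP (SD, n = 3 each), a log2 fold change of -4.58 (SE 0.90, edgeR adjusted p = 0.00168). It too varied among the sedentary libraries, at 59.4, 3.46 and 23.1 CPM in Sed replicates 1, 2 and 3. The log2 fold change was -3.46 without Sed replicate 1 and -5.25 without EHP replicate 2. It passed the test in all 15 alternatives, with adjusted p values of up to 0.0141.

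**Figure D2:**
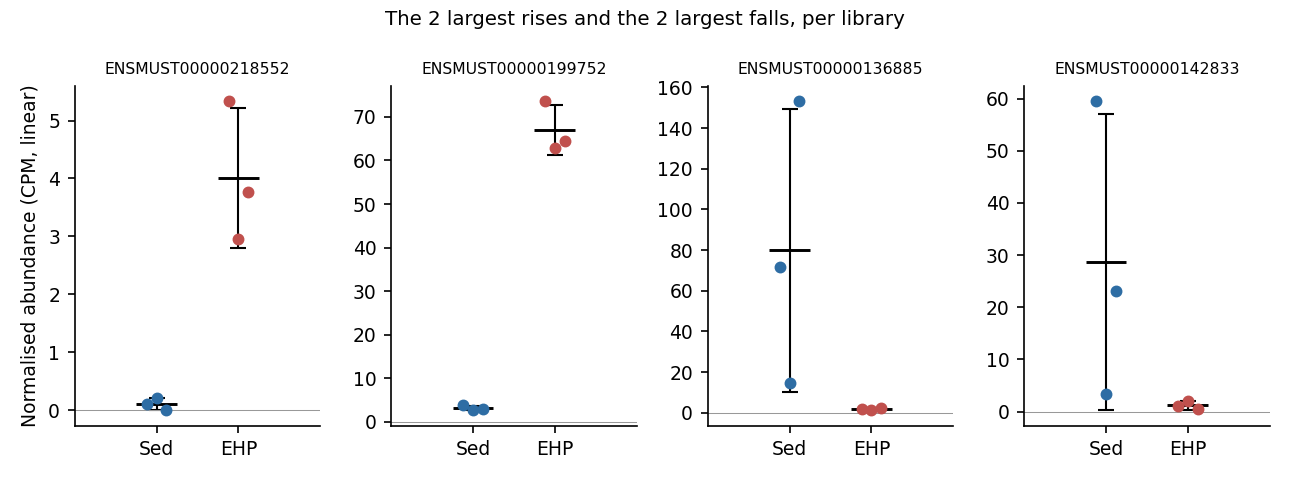
Normalised abundance in CPM (vertical axes, linear, a scale per panel) of the 4 named transcripts in the 3 Sed libraries (blue) and the 3 EHP libraries (red), 1 point per library. Horizontal bars are means and error bars are SD; the 3 EHP points lie wholly above or below the 3 Sed points in each panel, and the 2 falling transcripts scatter widely in Sed.

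The 10 largest rises that met the naming rule ranged from 11.6-fold to 32.4-fold, and the 10 largest falls from 6.25-fold to 42.1-fold. Among the 10 falls, the highest Sed library exceeded the lowest by over 3-fold for 8 transcripts, and in 6 of these 8 Sed replicate 2 was the lowest. A range of over 3-fold among the EHP libraries was seen for 3 of the 10. These transcripts were picked by the size of the fall, which a single high Sed library also raises.

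The most abundant transcripts changed too. Of the 20 with the highest mean abundance, 9 rose, 3 fell and 8 did not pass the test. Shares below are of the counts assigned to the 46746 listed transcripts, not of all RNA in the heart. The most abundant of the 20 took 4.85 ± 0.64% of these counts in EHP and 4.40 ± 0.33% in Sed (SD, n = 3 each). It did not pass (edgeR adjusted p = 0.328). The next in rank rose 1.70-fold (edgeR adjusted p = 0.000126), from 1.65 ± 0.11% to 2.79 ± 0.33% of counts. The transcript ranked 3 by abundance fell 4.37-fold (edgeR adjusted p = 2.08e-08), from 2.95 ± 0.26% of counts in Sed to 0.673 ± 0.049% in EHP. The transcript ranked 10 rose 5.03-fold (edgeR adjusted p = 9.9e-09), from 0.164 ± 0.017% to 0.821 ± 0.064%. It was the 1 rise of at least 2-fold among the 20. The second fall of at least 2-fold was the transcript ranked 14, which fell 7.89-fold (edgeR adjusted p = 0.000707). It varied among the sedentary libraries, with 104794, 12797 and 35272 counts in Sed replicates 1, 2 and 3. Its counts in the EHP libraries were 5694, 4606 and 3834. Its log2 fold change was -2.98, and -1.96 without Sed replicate 1. These transcripts were picked by abundance after the table had been seen.

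Direction changed with abundance. The tested transcripts were ranked by mean abundance and cut into 4 classes of 5011. In the scarcest class, at 1.08 to 3.87 CPM, 682 rose and 162 fell. In the next class 1016 rose and 646 fell, in the one after it 1003 rose and 1237 fell, and in the most abundant class, above 34.3 CPM, 1038 rose and 1672 fell. Increases of at least 2-fold outnumbered decreases in each class, with 550 against 128 in the scarcest and 156 against 93 in the most abundant. The median log2 fold change was 0.33 in the scarcest eighth and -0.08 in the most abundant eighth. Measured per library, as the deviation from the mean of all 6, the scarcest eighth minus the most abundant eighth was 0.22 ± 0.10 in EHP and -0.16 ± 0.06 in Sed on the log2 scale (SD, n = 3 each). All 3 EHP libraries lay above all 3 Sed libraries, with an exact two-sided permutation p of 0.1, the smallest possible.

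**Figure D3:**
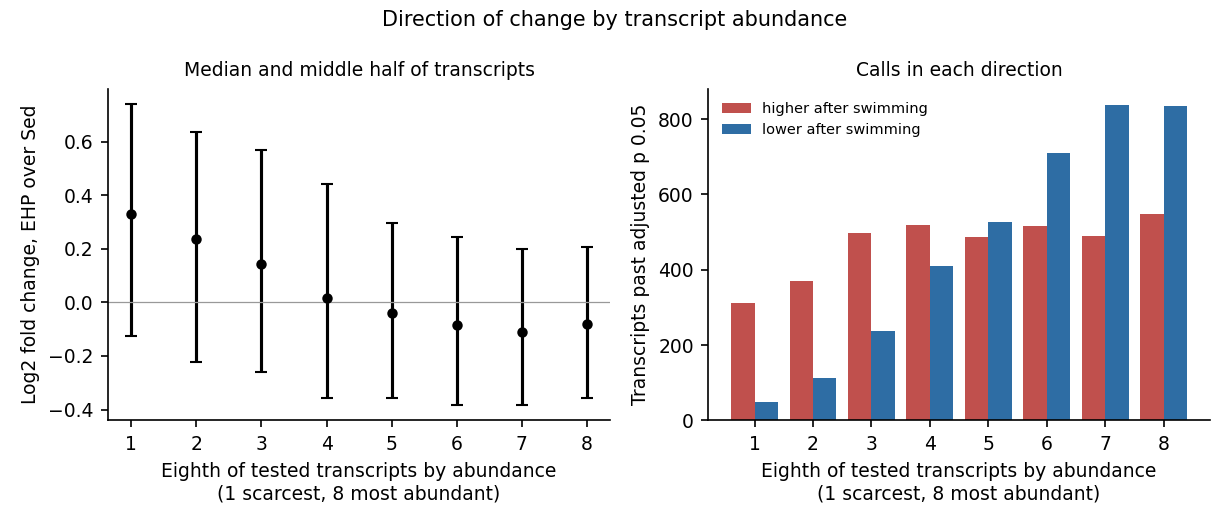
Left, median log2 fold change (EHP over Sed) of tested transcripts in 8 abundance classes, with bars from the lower to the upper quartile. Right, the number of transcripts past adjusted p 0.05 in each class that rose (red) or fell (blue); rises outnumber falls in classes 1 to 4, and falls outnumber rises in classes 5 to 8.

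The authors' deposited table gave 6022 transcripts with an adjusted p under 0.05, of which 2669 were higher and 3353 lower in EHP. At 2-fold or more, the authors' deposited table held 1037 higher and 491 lower transcripts. Its adjusted p was missing for 5949 of 27884 listed transcripts. All 20044 transcripts tested here were listed in the authors' deposited table, and across them its log2 fold changes and the edgeR values had r = 0.99998, with the same sign for 97.0%. The edgeR values were higher than those in the authors' deposited table by a median of 0.04 on the log2 scale. Both sets of values rest on the same libraries, so their closeness is no independent evidence for either. Of the 7456 edgeR calls, 5912 were also calls in the authors' deposited table, with 0 in opposite directions. A further 1544 were called by edgeR alone, 46 tested transcripts were called in the authors' deposited table alone, and 64 of its calls had too few counts to be tested here. For the 4 named transcripts the authors' deposited table gave log2 fold changes of 5.17 for ENSMUST00000218552, 4.33 for ENSMUST00000199752, -5.45 for ENSMUST00000136885 and -4.62 for ENSMUST00000142833.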

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

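Equal depth, DESeq2 on the transcripts of the authors' table and the fit without the 50 most abundant transcripts were chosen after seeing the data; the other settings were fixed before. The 7456 calls stayed within 1.5 times under each setting: 6056 with DESeq2, 7490 and 7472 with other scalings, 7787 with no filter, 7394 with a mean count of at least 10, 9173 at adjusted p under 0.1, 7165 at equal depth, 6094 with DESeq2 on the authors' transcripts and 7423 without the 50 most abundant. Leaving out 1 library gave 5652 to 6796 calls, the fewest without EHP replicate 3. The share of calls that were higher in EHP ranged from 43.9% to 50.6%, so which direction held the majority depended on the setting. Among calls of at least 2-fold, rises numbered 1000 to 1406 and falls 419 to 670. Each of the 4 named transcripts kept its direction and stayed past the threshold in 15 alternatives. The first principal component held 42.2% of the variance with no filter, against 60.4%; the cause was not tested. Without 1 library it held 58.3% to 63.0%, and the groups stayed apart on it in each case. Under the unadjusted p, the authors' deposited table held 8379 calls against 6022. The replicate numbers did not pair the libraries: deviations from the group means correlated at -0.01 to 0.05 for equal numbers and -0.09 to 0.07 for unequal ones, and not every library correlated best with its own number. The fit with the replicate block gave 7304 calls and changed no call of a named transcript. The planned results on Mhrt, the lncRNA subset and the gene lists were not run, since no gene names were attached. At this depth a transcript under 3 counts per library, or 0.314 to 0.457 CPM, could not be told from 0.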

Other observations

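The tests below were written down before their own results were seen, except that the patterns themselves, the neighbour counts, the windows and the spread within groups were chosen after the data had been examined.

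Neighbouring rows of the count table tended to move together between trained and sedentary hearts. The correlation of log2 fold changes between adjacent tested rows was 0.24, while the highest of 100 shuffles of the row order gave 0.02. Transcripts are not independent replicates, so this r describes the table only. Calls of equal direction stood side by side 2330 times, against at most 1474 in 100 shuffles, and calls of opposite direction 798 times. The steepest stretch of 25 neighbouring tested rows held 13 transcripts that rose and 0 that fell, with a mean log2 fold change of 1.15 and a median of 0.53; 12 of the 25 were not called. It held 3 of the 10 largest rises that met the naming rule, but it was picked for its high mean, which such rises lift. The highest mean of a stretch in 100 shuffles was 0.74. The lowest stretch had a mean of -0.66 and a median of -0.47, with 14 falls and 2 rises, against a mean of -0.52 in the shuffles.

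Reads shared between neighbouring transcripts are a candidate explanation for the joint movement of neighbouring rows, as isoforms and overlapping transcripts have rows of their own. If so, chance deviations of single libraries from their group mean should be shared between neighbours as well. Their correlation was 0.0945 for adjacent rows, between the 0.05 and 0.1 set beforehand as bounds for neighbours. At a distance of 2 rows, for which no bound was set, it was 0.0423. The value for adjacent rows thus fell between the bounds. Joint regulation that varies between libraries would share deviations too, so even a value above 0.1 would not have separated it from shared reads. No positions were attached to the rows, so whether neighbouring rows lie close in the genome was not examined. Shared reads and joint regulation of neighbouring rows therefore cannot be told apart here. A count of called transcripts is in either case not a count of independent events.

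The 7456 calls between trained and sedentary hearts are many for 3 libraries a group. Thinning argues against unequal totals as such as their source. With every library thinned to the smallest total, 7165 transcripts were called, and 6907 of the original calls remained. Thinning keeps the proportions within each library, so differences that arose before counting were not tested by it. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many calls, the real one. The highest of the 9 other splits gave 0 calls by edgeR, with 188 to 519 transcripts at an unadjusted p under 0.05 across them. By DESeq2 the 9 gave 0 to 2 calls. Each of them put libraries of both groups on each side, so the group difference entered the spread and lowered the calls. Their counts are therefore no estimate of false calls between the real groups. In addition, 10 splits are too few for a share under 0.05. A difference in handling or sequencing between the 2 groups stays open and untested beside the training itself, because no label separates them.

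Scarce transcripts tended to be higher and abundant ones lower in trained hearts, a difference of 0.41 between the median log2 fold changes of the scarcest and the most abundant eighth. Unequal totals as such do not account for it. At equal depth the difference was 0.376, above the 0.2 set beforehand. It was between 0.32 and 0.50 over the 15 alternatives. Thinning could remove only bias from small counts, so effects of depth that arose before counting stay untested. Simulated counts with these depths and no such trend gave -0.01. Diffuse background reads in the trained libraries may contribute, but how large a background the trend would need was not estimated. The transcripts too scarce to be tested, which took no part in the trend, held 0.576 ± 0.059% of counts in EHP and 0.488 ± 0.024% in Sed (SD, n = 3 each), a ratio of 1.181, with each EHP library above each Sed library and an exact permutation p of 0.1, the smallest possible. A true rise of scarce transcripts after training predicts the same and stays open, as does handling that differed between the groups.

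Sedentary libraries were further apart than trained ones among abundant transcripts. Over the 2844 transcripts with a mean of at least 500 counts, the median range from the lowest to the highest library was 0.197 in Sed and 0.155 in EHP on the log2 scale. The highest library exceeded the lowest by over 2-fold for 30 in Sed and 6 in EHP, and by over 3-fold for 7 in Sed and 1 in EHP. Whether these numbers differ beyond chance was not tested.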
